A study of Mus musculus with 2 samples.

How the data were processed

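Total RNA from 1 Lsh wild type and 1 Lsh knockout mouse embryonic fibroblast (MEF) line was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array per genotype, per the labels' protocols. Lsh is the product of the gene Hells. RNA was extracted with Trizol and labelled with biotin after conversion to cDNA, per the labels' protocols. The authors deposited 1 table of log2 expression values made with RMA (robust multi-array average: background correction, quantile normalization and median-polish summary of the probes), per the submitters' processing notes; its version and settings, the probe grouping and the genome build were not given in the sources used here. That the deposited values are log2 was read from their range, which ran from 0.89 to 13.1. The table held 23950 rows, of which 64 were Affymetrix control probe sets and 23886 carried a RefSeq transcript accession in place of the array's own probe set name, so the values had been summarised by transcript before deposit. Scanner intensities and detection calls were not used here, and so the background level of each probe was not known.

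The accessions were matched without version to the transcripts of the GRCm38.p6 gene table; 21230 rows matched 1 gene and 2656 matched none; of the unmatched rows 735 passed the dimness limit given next, 35 of them at least 2-fold higher and 36 at least 2-fold lower, and they were left out of the gene counts. No coordinates are given, because the build behind the deposited rows was not stated; the gene table supplied symbols, chromosomes and the order of neighbouring genes. The matched rows named 16579 genes. Transcripts of 1 gene often held identical values, as rows made from the same probes would, and 1105 rows held exactly the same value on both arrays. Each gene was represented by the row with the highest mean of both arrays. A gene was kept where the higher of its 2 values was at or above the median of all rows on that array, 3.86 for the wild type and 3.88 for the knockout; 9168 genes were kept and 7411 were not. This dimness limit is not a detection limit. Where the dimmer array lay below it, the brighter value over the limit is given as an "at least" fold.

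Differences are knockout minus wild type on the log2 scale. With 1 array per genotype there was no replicate, no spread within a genotype and no p-value, so genes were counted and named by size alone, with 2-fold as the threshold. Of 22 fixed gene lists (676 entries, 624 of them measured), 16 had at least 5 kept members. The median difference of each of these was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called higher or lower where its median lay outside the central 95% of the random medians. By chance 0.8 of 16 lists would do so if genes varied independently of each other. Lists whose members vary together would do so more often, so the calls cannot be weighed against that number. The genes of each chromosome were placed among random sets in the same way. These percentiles describe the 2 arrays, and not the genotypes.

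The genes named were the 12 farthest apart in each direction, Hells, and up to 3 members of each list in each direction at 2-fold or more, or otherwise the member farthest from 0. The Y-linked genes, Xist and the reference genes were named in any case. Some genes that this rule takes are not reported here. The lists, the rule, the threshold and the alternatives, apart from those named as chosen later, were fixed before the data were examined. Ifit1, Rrm2, Rian, Bmi1, Cxcl1, Cdkn2b, Mylk, Col1a1, Col3a1, Fn1, Vim, Sparc and Cdkn2a were named in the results after their values were seen, as were the genes of the closing observations that the rule does not name.

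The counts and the list calls were tested on simulated data for the 9168 kept genes, with a noise SD of 0.51 taken from the central spread of the real differences. Of 50 genes simulated 3 log2 units higher, 50 were counted, and of 50 simulated 1.5 log2 units higher, 37 were. Of 8968 genes simulated with no difference, 439 passed 2-fold, so that the 2-fold counts can hold that many genes if the whole central spread is noise. All 10 lists of 20 genes shifted by 0.5 were called, as were 2 of 40 lists without a shift. The simulated noise was normal, with the same SD for every gene and independent between genes. Larger noise of dim genes, and genes that vary together, were therefore not covered by these numbers.

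Alternatives were the mean over a gene's rows, no dimness limit, a limit at the upper quartile, quantile normalization of the deposited columns, removal of an intensity-dependent trend by loess (span 0.3), a pseudocount of 32 on the linear scale, and thresholds of 1.5-fold and 3-fold. Chosen after seeing the data were counting genes of identical values once, subtracting chromosome medians and scaling the knockout array to the hybridisation controls. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.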

Results

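The expression profile of mouse embryonic fibroblasts lacking Lsh, a chromatin remodelling protein of the SNF2 helicase family required for normal DNA methylation, was compared with that of wild type fibroblasts. The series set out to relate cytosine methylation at non-repetitive sequence to gene expression, and the arrays supply the expression side. Each genotype was measured on 1 array, and this number limits the precision of every value below. The deposited values had a median of 3.86 on the wild type array and 3.88 on the knockout array, and across the 9168 kept genes the arrays correlated with r = 0.89. Genes are not independent replicates, so this r describes the arrays only.

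Hells, which encodes Lsh and was the gene knocked out, was 2.75-fold lower in the knockout. Its only row (NM_008234) read 6.68 in the wild type and 5.22 in the knockout, a difference of -1.46 (-0.96 with a pseudocount of 32 on the linear scale), and the knockout value lay above the dimness limit of 3.88. Whether the probes of this row lie in the deleted part of the gene is not given in the sources used here. If they lie outside it, the row checks nothing about the labels.

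Control probe sets and reference genes set the technical background of the comparison. The 10 kept reference genes had a median difference of -0.10, within the range of matched random lists, and extended from -0.48 for Gusb to 0.28 for Tbp. Sdha differed by 0.09, Psmb4 by -0.07, Ywhaz by -0.08, Hprt by -0.12, Rpl13a by -0.33 and Actb by -0.34, while Tfrc lay below the dimness limit on both arrays. The 3′ control probe set of Actb exceeded its 5′ probe set by 2.56 in the wild type and by 3.15 in the knockout, and that of Gapdh by 2.14 and 2.84, so this 3′ to 5′ gap, a sign of RNA integrity, was wider in the knockout by 0.60 and 0.70. The gaps of the other such controls were narrower in the knockout, by -0.59 for 18S ribosomal RNA, -0.35 for pyruvate carboxylase and -0.24 for the transferrin receptor. The transferrin receptor lay below the dimness limit at both ends and pyruvate carboxylase at its 5′ end. Among controls above the limit at both ends, Actb and Gapdh thus had wider gaps, and only 18S, a ribosomal RNA, had a narrower one. The 9 hybridisation control probe sets of the newer design (bioB, bioC, bioD and cre), which report RNA added to the hybridisation at a fixed amount, were higher on the knockout array by a median of 0.44 (from 0.21 to 0.78). The dap and lys control probe sets above the dimness limit went the other way, at -0.71, -0.37 and -0.42. These were dim, at 4.48 to 5.33 in the wild type, and all other dap and lys probe sets lay below the limit. They thus say little about the direction of a scaling. The older bioB, bioC, bioD and cre probe sets were all higher on the knockout array too, from 0.18 to 0.85. Scaling the knockout array to the hybridisation controls moved the median of all kept genes by -0.45 and put all 10 reference genes below 0, so each direction given is relative to the other genes on these arrays.

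Xist, the RNA that coats the inactive X chromosome, read 7.52 in the wild type and 7.82 in the knockout. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay between 1.34 and 1.68 on both arrays, below the dimness limit.

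Of the 9168 kept genes, 426 were at least 2-fold higher in the knockout and 556 at least 2-fold lower. At 8-fold or more, 32 genes were higher and 42 lower. In 178 of the 426 higher genes the wild type value lay below the dimness limit, and in 226 of the 556 lower genes the knockout value did. Scaled to the hybridisation controls, the counts became 168 higher and 1349 lower. The quartiles of the differences were -0.34 and 0.35. Of 33 genes past 2-fold with a further row holding other values, all 33 had that row on the same side and 28 had it past 2-fold too, though such rows can share probes.

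**Figure D1:**
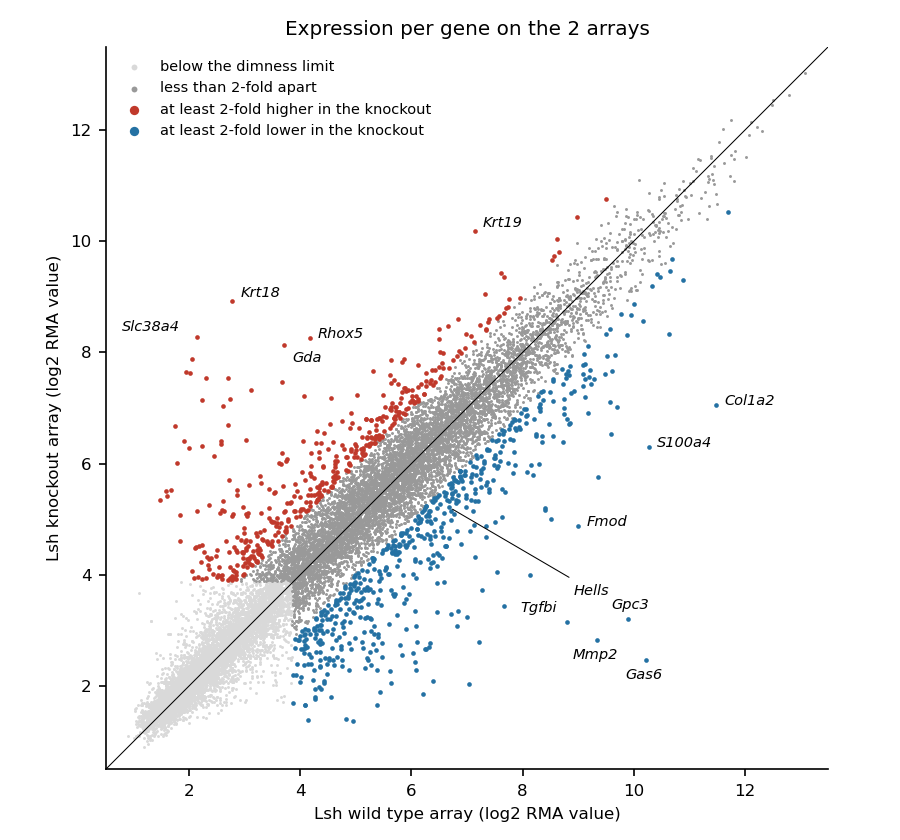
Log2 RMA value of each gene on the wild type array (x axis) and on the knockout array (y axis), 1 point per gene; the line marks equal values. The 426 genes at least 2-fold higher in the knockout are red, the 556 at least 2-fold lower are blue, and Gas6, Gpc3 and Mmp2 lie lowest on the right.

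The 12 genes highest in the knockout, among rows matched to a gene, had wild type values below the dimness limit; 1 unmatched row, at 5.80, lay among them. Krt18, a keratin of simple epithelia, read 2.77 in the wild type and 8.92 in the knockout, a measured difference of 6.15 and at least 33.4-fold over the dimness limit. Slc38a4, an imprinted amino acid transporter, read 2.14 in the wild type and 8.28 in the knockout (at least 21.4-fold), and Gda, a guanine deaminase, 3.71 and 8.14 (at least 19.4-fold). Cox7b2 and Rpl39l, relatives of a cytochrome oxidase subunit and of a ribosomal protein that are mainly expressed in testis, reached 7.88 and 7.64, at least 16.3-fold and 13.8-fold. Prxl2a, AI662270 and Rundc3b reached 7.63, 7.54 and 6.40, at least 13.7-fold, 12.8-fold and 5.84-fold. The other 4 of the 12 highest genes, 4930550L24Rik, Dcaf8l, Efhc2 and Gm364, were X-linked and reached 7.55, 6.67, 7.14 and 7.03, at least 12.9-fold, 7.02-fold, 9.72-fold and 9.02-fold. The wild type values of the 12 lay between 1.74 and 3.71.

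The genes lowest in the knockout included several secreted and matrix proteins. Gas6, a secreted ligand of the TAM receptor kinases, read 10.2 in the wild type and 2.46 in the knockout, at least 81.0-fold lower. Gpc3, a heparan sulfate proteoglycan encoded on the X chromosome, went from 9.90 to 3.19 (at least 64.6-fold), Mmp2, a matrix metalloproteinase, from 9.35 to 2.82 (at least 44.1-fold), and Tgfbi, a TGF-beta-induced matrix protein, from 8.79 to 3.14 (at least 30.1-fold). Col1a2, a chain of type I collagen, was measured above the limit on both arrays at 11.5 and 7.06, a difference of -4.43 or 21.5-fold, and so was the proteoglycan Fmod at 9.01 and 4.87 (17.6-fold) and Tmem88 at 8.14 and 3.99 (17.8-fold). The chemokine Cxcl14, the xanthine dehydrogenase Xdh, the actin regulator Cobl, the carboxylesterase Ces2g and the secreted protein Cthrc1 were at least 8.91-fold, 10.0-fold, 13.8-fold, 5.67-fold and 4.99-fold lower.

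Fibroblast and matrix genes were lower in the knockout as a list. Of 35 kept members 15 were at least 2-fold lower, 1 was at least 2-fold higher and 19 lay between, and 33 had differences below 0. Besides Col1a2 and Fmod, the fibroblast marker S100a4 was 15.8-fold lower, at 10.3 and 6.29. Col1a1, also a chain of type I collagen, differed by only -0.73, and Col3a1 by 0.78. The collagen receptor Ddr2 was 2.61-fold higher, and Fn1, Vim and Sparc differed by -0.03, -0.09 and -0.21. The list median was -0.88, and all 10000 matched random lists lay above it. In the same sample the 3′ to 5′ gap was wider for Actb and Gapdh (0.60 and 0.70) and narrower for 18S and pyruvate carboxylase (-0.59 and -0.35). The pyruvate carboxylase 5′ values, 3.44 and 3.45, lay below the dimness limit on both arrays, which limits that gap.

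Smooth muscle and myofibroblast markers were lower as well, with a median of -0.82 over 11 kept members that none of 10000 random lists reached. Over all 17 measured members, with no limit, the median was -0.26 at percentile 0.815. Myl9, a myosin light chain, was 11.5-fold lower, the actin-binding protein Tagln 6.41-fold, calponin Cnn1 3.82-fold and the kinase Mylk, the fourth member past 2-fold by its measured difference, at least 2.67-fold. The remaining 7 members lay within 2-fold, and 10 of the 11 had differences below 0. The 3′ to 5′ gaps of the controls apply here too. Among controls above the dimness limit at both ends, they were wider in the knockout for Actb and Gapdh and narrower for 18S ribosomal RNA.

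Germline genes, which in somatic cells are commonly held silent by DNA methylation, were higher in the knockout, with a median of 1.90 over 9 kept members, which 1 of 10000 random lists reached. Of the 9, 6 were kept by their knockout value alone, and over all 42 measured germline genes, with no limit, the median was 0.18 at percentile 99.9, below those of the cell cycle (0.39) and interferon (0.34) lists. Of these 9, 6 were at least 2-fold higher, 3 lay within 2-fold and none was 2-fold lower. Rhox5, an X-linked homeobox gene of the reproductive tract, was 17.0-fold higher, at 4.17 and 8.26. Magea5 reached 5.35 from below the limit and Tex101 went from 2.44 to 6.13, at least 2.81-fold and 4.84-fold over the limit. A further 33 measured members of this list lay below the limit on both arrays, so most of the list stayed dim.

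Cell cycle genes were higher relative to other genes, by a median of 0.41 that became -0.031 after scaling to the hybridisation controls. Of 43 kept members 35 had differences above 0, and none of 10000 random lists reached their median. The replication factor Cdc6 was 2.34-fold higher, the replicative helicase subunit Mcm6 2.30-fold, the kinesin Kif20a 2.10-fold and the ribonucleotide reductase subunit Rrm2 differed by 1.04. The other 39 members lay within 2-fold.

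Interferon response genes had a median of 0.38 over 22 kept members (-0.061 after scaling to the hybridisation controls), which 89 of 10000 random lists reached. The guanylate-binding proteins Gbp2 and Gbp3 were at least 7.13-fold and 2.44-fold higher, Oasl2 at least 2.12-fold and Ifit1 at least 1.15-fold over the limit. The immunoproteasome subunit Psmb8 was lower, by at least 1.52-fold over the limit, and 17 members lay within 2-fold. After the median of each chromosome was subtracted, the list median was 0.20 and lay within the random range. With the limit at the upper quartile 8 members remained, whose median was also 0.38 but lay within the random range, at percentile 87.9.

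Imprinted genes, which are expressed from 1 parental allele under the control of DNA methylation, differed in both directions. Their median was -0.23, at percentile 1.66 of the random lists, while their mean was 0.13, because a few members were much higher. Of 48 fixed members 46 were matched to a row, and H19 was not among them, so the median and the call leave it out. The unmatched rows, the highest at 5.80, carried no gene name here, and whether 1 of them measured H19 was not examined. Slc38a4 was given above, Ndn went from 2.00 to 6.29 (at least 5.38-fold) and Ppp1r9a was 2.56-fold higher. Grb10 was at least 2.81-fold lower over the limit, Igf2 3.35-fold lower, Igf2r 2.52-fold lower and Rian differed by -1.19. The call was lost without a limit (-0.038), with the pseudocount (-0.14) and with the limit at the upper quartile, where the median was 0.074.

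The other lists, apart from the protocadherin genes, lay within the range of random lists. Hox genes, regulators of axial patterning, had 11 kept members and a median of 0.16. Hoxa5 was 2.65-fold higher, whereas the neighbouring Hoxb2, Hoxb3 and Hoxb4 had differences of -2.73, -1.83 and -1.08, at least 2.79-fold, 1.87-fold and 1.32-fold over the limit. Senescence and secretory genes (median -0.20, 23 kept) held 5 members at least 2-fold higher and others at least 2-fold lower. The higher ones were Igfbp5 with a difference of 2.00, Mmp3 at least 3.32-fold, Igfbp2 at 2.73-fold, and Bmi1 and Cxcl1 with differences of 1.29 and 1.15. Among the lower ones, Igfbp7 was 4.92-fold lower, Cxcl12 3.85-fold and Cdkn2b differed by -1.48, while Cdkn2a, which encodes p16 and p19Arf, differed by 0.18. Regulators of DNA methylation and chromatin had a median of 0.15 over 35 kept members, with Ezh2, the Polycomb methyltransferase, alone past 2-fold at 2.69-fold higher; this list stood above the random range with the limit at the upper quartile (0.30) and after quantile normalization (0.26). No p53 target among 22 kept members passed 2-fold, and the farthest from 0 was Trp53inp1 at 0.81. Of 6 kept pluripotency genes, Dppa4 was at least 2.36-fold higher and Tfcp2l1 at least 1.82-fold lower. The 21 kept protocadherin genes, of which Pcdhga1 is 1 example, all carried a single measured value with a difference of -0.43, so this list is 1 measurement and its call, at percentile 0.15, is not that of a list.

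Markers of other cell types had medians within the random range, at 0.26 for epithelial, -0.12 for adipocyte and -0.49 for skeletal muscle markers. Of 8 kept epithelial and keratinocyte markers, Krt18 and Krt19 (8.27-fold) were higher, Krt15 was 3.41-fold lower and 5 lay within 2-fold, and 20 measured members were below the limit on both arrays. The adipocyte markers, 7 kept, included Lpl at 3.56-fold higher, Scd1 at 2.84-fold lower and Lipe at 2.01-fold lower. The skeletal muscle markers, 6 kept, included Tnnc1 at least 2.86-fold lower and Pax3 at 2.09-fold lower. Fewer than 5 members were kept for 4 further marker lists, for which only values are given. Among these the endothelial receptor Kdr was 3.52-fold higher and Egfl7 3.32-fold lower, Spp1 2.80-fold higher and Alpl 2.09-fold lower in the cartilage and bone list. The neural adhesion molecule Ncam1 differed by -0.76, and Itgb2 of the blood cell list by -0.44, at least 1.30-fold over the limit.

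**Figure D2:**
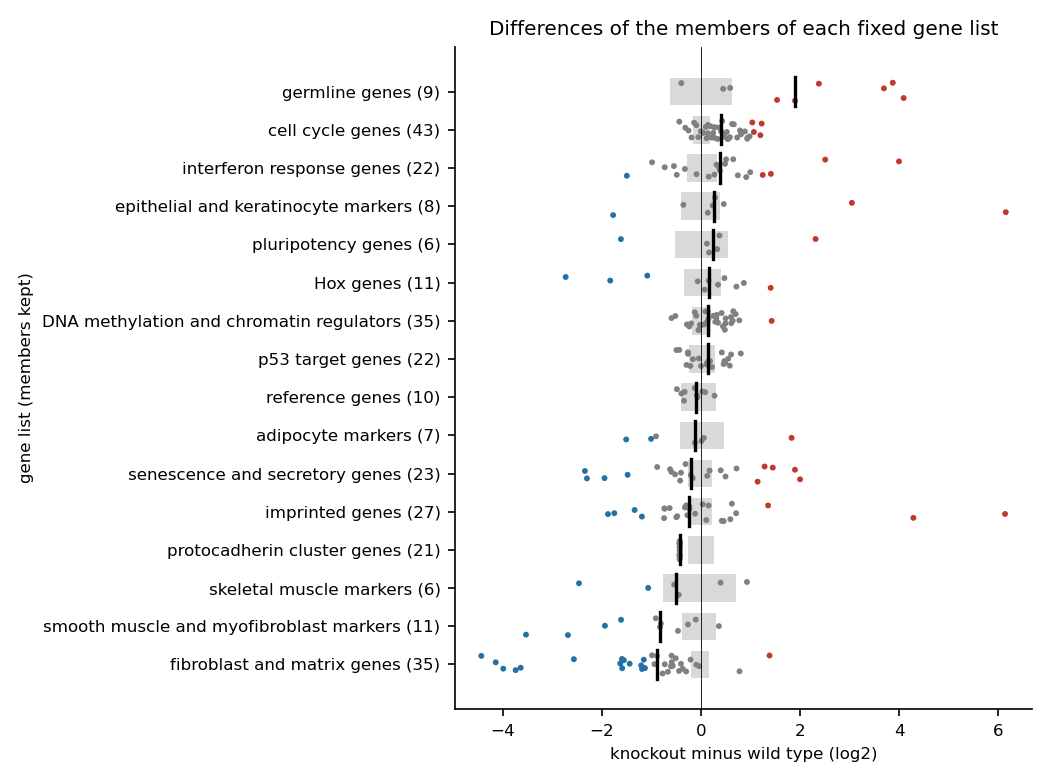
Knockout minus wild type difference (x axis, log2) of each kept member of the 16 gene lists (y axis, number of kept members in brackets); red and blue points are at least 2-fold higher and lower, black bars are list medians and grey boxes hold the central 95% of medians of matched random lists. Fibroblast and matrix genes have the lowest median, -0.88, and the 9 kept germline genes the highest, 1.90, which was 0.18 over all 42 measured members.

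The genes of whole chromosomes were shifted in both directions relative to the other genes. Scaling to the hybridisation controls lowers every knockout value by the same 0.44, which put all 20 medians below 0. It left the chromosomes in the same order, so these signs say nothing about single chromosomes. Chromosome 18 had the highest median, 0.42 over 240 kept genes (-0.016 after that scaling), with 72.5% of them above 0, followed by chromosome 6 at 0.28 over 449 genes and chromosome 11 at 0.18 over 817. Chromosome 16 had the lowest median, -0.16 over 280 genes, followed by chromosome 4 at -0.14 and chromosome 2 at -0.12. Of 20 chromosomes, Y left out, 7 lay above and 8 below the central 95% of matched random sets. The call of chromosome 5 was lost under 5 alternatives, that of chromosome 17 under 2, and those of chromosomes 3, 7 and 16 without a limit. Chromosome X had a median of 0.00 over 252 genes and lay within it. The 14 kept rows placed on chromosome Y held only 2 distinct measurements, and their call is not used.

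**Figure D3:**
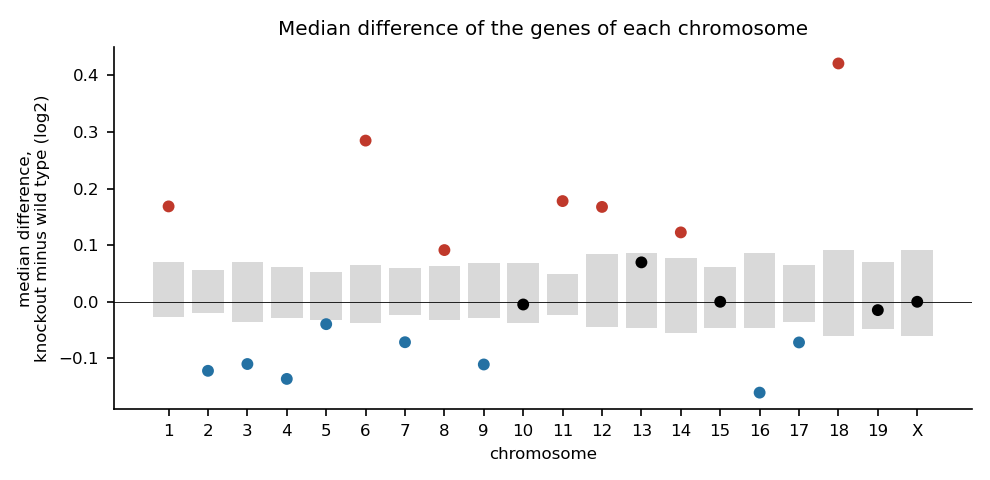
Median knockout minus wild type difference (y axis, log2) of the kept genes of each chromosome (x axis); points are red above, blue below and black within the grey boxes, which hold the central 95% of medians of matched random gene sets. Chromosome 18 stands highest at 0.42 (-0.016 after scaling to the hybridisation controls) and chromosome 16 lowest at -0.16.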

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

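No paired analysis was possible because each genotype had 1 array, and no replicate could be left out for the same reason. Leaving out rows whose names end in _s_at or _a_at was not run, since no transcript row had such a name, and the mean over rows gives no agreement between rows. Counting identical values once, subtracting chromosome medians and scaling to the hybridisation controls were chosen after seeing the data. The counts of 426 higher and 556 lower genes became 225 and 314 with the limit at the upper quartile, 101 and 193 with the pseudocount of 32, 1254 and 1267 at 1.5-fold, 131 and 240 at 3-fold, and 168 and 1349 with the knockout array scaled to the hybridisation controls; the share of higher genes among them, 43.4% as first set, was 34.4% with the pseudocount and 11.1% with that scaling, which moved the median of all kept genes by -0.45. The stricter limits and thresholds count fewer genes by construction. Hells stayed lower but was -0.96, under 2-fold, with the pseudocount. The imprinted list lost its call without a limit (-0.038) and with the pseudocount (-0.14), and turned to 0.074 at the upper quartile. The interferon list was within the random range at the upper quartile (0.38) and after subtraction of chromosome medians (0.20). The chromatin regulators passed into the higher range at the upper quartile (0.30) and after quantile normalization (0.26). Chromosome 5 was within the range with the mean over rows (-0.029), at the upper quartile (-0.077), after quantile normalization (-0.012) and after loess (-0.047), and chromosome 17 at the upper quartile (-0.082). Without a limit the medians of chromosomes 3, 5, 7, 16 and 17 were 0, where dim rows of identical value on both arrays enter. For these results the cause was otherwise not tested. The calls of the fibroblast, smooth muscle, germline and cell cycle lists held under every alternative run for them (the germline list at the upper quartile and the protocadherin list with identical values counted once had too few members for a value), but without a limit the germline median was 0.18 and the smooth muscle median -0.26, and with the pseudocount the germline, cell cycle and interferon medians were 0.47, 0.26 and 0.19. No named gene past 2-fold changed direction under the settings run for single genes; 28 values of single named genes were under 2-fold, with the pseudocount or the hybridisation scaling (chromosome medians were not subtracted for single genes), and Ncam1 passed it with that scaling (-1.20). Detection calls were not used here, so low values limit every fold that starts or ends below the dimness limit.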

Other observations

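Apart from the lists fixed in advance, several single genes chosen after their values were seen stood out on the 2 arrays. The helicase Ddx25 was at least 5.04-fold higher over the dimness limit, Mns1 at least 2.58-fold, the testis cytochrome c Cyct at least 1.57-fold, Ccnb1ip1 at least 1.30-fold and Gpat2 at least 1.15-fold, while 33 of the 42 measured members of the germline list lay below the limit on both arrays. The plasma retinol carrier Rbp4 was higher, at 2.63, and the retinaldehyde dehydrogenase Aldh1a2 at least 4.57-fold higher over the limit. The developmental regulator Lhx2 was at least 4.44-fold higher and the Polycomb-associated gene Sfmbt2 at least 5.66-fold. The basement membrane collagens Col4a1 and Col4a2 were lower, at -1.71 and -1.40, as were the antigen presentation genes H2-T23, at least 7.76-fold, and Tap2, at least 2.27-fold.

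The explanations were tested on the arrays in which the patterns were found. The tests of X-linked genes, of RNA integrity and of copy number were chosen after the values they use had been seen.

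X-linked genes were frequent among the most strongly higher genes. Of 32 genes at least 8-fold higher by measured difference, 9 were X-linked (4930550L24Rik, Dcaf8l, Efhc2, Gm364, Rhox5, Dcaf12l1, Magea5, Nxf3 and 3830417A13Rik), against a mean of 0.99 in draws matched on mean expression, and 0 of 10000 draws held as many, which argues against these genes being X-linked by chance, although Gm364, 4930550L24Rik and 3830417A13Rik are neighbours and not independent (7 with neighbours counted once, above the 6 that the highest draw held). More X-linked transcription as a whole in the knockout line is argued against by the median difference of 0 over the 252 kept X-linked genes, inside the random range of -0.06 to 0.09. In order of position, 4 equal segments of these genes had medians of 0.25, 0.009, -0.038 and -0.26. A difference of parts of the X chromosome was not tested and stays open. Noise of dim genes would not favour the X chromosome among genes of matched expression. The same draws, of which 0 held 7, are not a separate test of noise, since the highest held 6. Knockout values of the 9 genes ran from 5.07 to 8.26. At 2-fold, 16 X-linked genes were higher and 18 lower. Loss of methylation at these genes in the absence of Lsh, the subject of the series, may account for the pattern but was not tested here, and a difference between the lines apart from Lsh stays open.

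The shifts of whole chromosomes concerned 15 of 20 chromosomes. A few genes far apart can hardly move the median of a whole chromosome. Without the genes past 2-fold 15 of the 15 stayed outside the random range on the same side, an outcome that a median all but fixes. After loess 14 of the 15 did. Loess moved the differences by a median of only 0.034, and the random sets were matched on mean expression. An intensity-dependent difference between the arrays was thus small, and the calls after loess add little. Copy number of whole chromosomes that differs between the lines stays open: in 12 of the 15, each of 4 equal segments of the genes in order of position lay on the chromosome's side of the median of all genes, but 1000 random orders of the genes gave 12 to 15 (central 95%), so the count decides nothing. On chromosome 18 the segments were at 0.44, 0.48, 0.47 and 0.48. Base composition was not tested and stays open.

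The lower level of fibroblast and matrix genes was uneven among the members. Dilution of the fibroblasts by another cell type would lower all members alike only if that cell type expressed none of them. The interquartile range of the members' differences was 1.10, above the 0.90 that bounds the central 95% of matched random lists. This argues against dilution by cells that express none of the members. Dilution by cells that express some of them stays open. Lower RNA integrity in the knockout sample stays open. The 3′ to 5′ gap was wider for Actb and Gapdh (0.60 and 0.70) but narrower for 18S and pyruvate carboxylase (-0.59 and -0.35). The pyruvate carboxylase 5′ values lay below the dimness limit on both arrays, which limits that gap. Of the members, 15 were lower by more than 0.99, the largest fall of a 5′ control probe set. Random lists held a mean of 1.62 and the central 95% reached 4. That size lies next to the 2-fold threshold, past which 15 members were lower. A list already found lower exceeds random lists there whatever the cause. The size also rests on few controls, so the count decides nothing about integrity. An intensity-dependent difference between the arrays is argued against by the small size of the trend. Loess moved the differences by a median of 0.034, and the list median only from -0.88 to -0.85. The random lists were already matched on mean expression, so the call could hardly change and adds nothing. A change in fibroblast state with the genotype and a difference between the lines apart from Lsh stay open, with 1 array each.

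Neighbouring genes may differ together more often than chance, as a hypothesis. Along the 20 chromosomes, 103 adjacent pairs of kept genes passed 2-fold in the same direction, against a mean of 58.1 and a highest value of 84 in 10000 random orders within chromosomes. Pairs, with measured differences that in part end or start below the dimness limit, included Cxcl14 and Tgfbi (-5.01 and -5.65), Irx5 and Mmp2 (-1.57 and -6.53), Rundc3b and Abcb1b (4.49 and 2.36) and Grb10 and Cobl (-1.87 and -4.22). Related neighbours that share probes could add pairs, and this was not tested beyond counting genes of identical values once.

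Zinc finger genes named Zfp may be higher in the knockout as a group relative to other genes, with Zfp979 at least 3.19-fold higher over the dimness limit. The 177 kept members had a median of 0.27 (-0.16 after scaling to the hybridisation controls), above the random range of -0.05 to 0.12, with 18 at least 2-fold higher and 3 at least 2-fold lower. Such genes lie in clusters of similar sequence, so that shared probes are a candidate source of part of this shift.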
